A study of Mus musculus with 8 samples.

How the data were processed

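Chromatin immunoprecipitation sequencing was done on untreated cells of the 3134 mouse mammary line with antibodies to Brg1 (a monoclonal antibody), CHD4 and Snf2h. The labels name 8 libraries: replicates 1 and 2 of each antibody and 2 DNA inputs. The inputs were not analysed here. The extraction text in the labels describes DNase I digestion of nuclei and lines with induced dominant-negative remodelers, which is another assay, so how the immunoprecipitation was done is not given in the sources used here. Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates came from separate cultures, so every measure of spread covers only these libraries and may be technical. No label says that a shared replicate number marks a shared batch or day, so numbers were not used to pair libraries in the main results.

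Reads were processed with CASAVA 1.6 and placed on mm9, per the submitters' processing notes, which do not give the role of CASAVA. The authors called hotspots in each library separately. The caller, the handling of inputs and the thresholds are not given in the sources used here. The deposited lists give each hotspot's maximum and average tag density, a signal whose scaling is not stated, and a score, the Z score of enrichment, per the file headers. Where the deposited p-value is above 0 it is the two-sided normal probability of that Z score, and recomputed values differed by at most 0.000654 on the log10 scale. It is listed as 0 for 303 to 13309 hotspots per list. Densities move in fixed steps that differ between lists, from 0.158 in Brg1 replicate 2 to 0.693 in Snf2h replicate 1, as values scaled by depth would, but the depth itself is unknown. Densities and scores are the authors' own and were mainly used to rank or filter hotspots within a list. The exceptions are ratios between chromosomes inside 1 list and a common Z score cut applied to all lists. Between libraries, ranks of density were compared and not densities. The smallest hotspot was 252 bp wide in every list, and between 7 and 178 hotspots per list overlapped a neighbour. All hotspots lay on the 19 autosomes and X.

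Intervals were read as closed and compared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Hotspots were shared when they overlapped by at least 1 bp. A replicated site is a merged region holding a hotspot of both libraries of an antibody. Replicated sites of the 3 remodelers were merged again, and each region was put in a class by the remodelers it held. The null for an overlap moved 1 set by a random circular shift within each chromosome, between the lowest start and the highest end found in the 6 lists, 1000 times. Its one-sided p counts shifts that reach the observed overlap and compares positions of lists, not conditions. For the classes, the CHD4 and the Snf2h sites were each shifted separately. Chromosome lengths are those same spans. Grouping by antibody was tested by exact enumeration of the 15 splits of 6 libraries into 3 pairs, whose smallest p is 0.0667. Shares carry 95% Wilson intervals, which cover counting error only.

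Before the data were examined, the groups, these tests and their alternatives were fixed, with a rule for naming regions: the 5 of highest mean within-list percentile of maximum density in the class of all 3 remodelers and in each class of 1 remodeler. The alternatives fixed then were the taller 50% of each list, lists of equal size (32310, the length of the shortest), an overlap of at least 50% of the shorter interval, sites from either library, leaving out each library, leaving out the tallest 1%, shifts of 100 kb to 1 Mb only, ranking by width, and pairs of lists with the same replicate number. The comparison of height order at common regions, the share of Brg1 regions with Snf2h, the X density of replicated sites and classes (that of single lists had been fixed), the other tests of the X chromosome, the common Z score of 9.49 and the 500 bp windows were chosen after seeing the data.

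Promoter overlap, occupancy of 13 fixed gene lists and content of 16 sequence motifs had been planned. They need an annotation or sequence of mm9, which was not used here, so they were not run and no gene is named from a coordinate.

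The overlap tests were tested on simulated data with site sets of the real sizes. For Brg1 and CHD4 with no planted sharing, the overlap was 2.42% against 2.40% after shifts. A planted share of 30% for Brg1 and Snf2h came back as 31.6%, and 70% for CHD4 and Snf2h as 70.5%. For the classes, 2000 planted regions of all 3 remodelers came back as 2014, and independent sets gave 15 against 9.01 after shifts (permutation p = 0.0594). The simulated intervals had a single fixed width and were placed evenly at random. Real replicated sites had median widths of 650 to 897 bp and were unevenly spread, and Brg1 and CHD4 gave 4.09% after shifts. The simulation therefore does not show how the test behaves with clustered sites.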

Results

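The series asked where the ATPases Brg1, CHD4 and Snf2h sit in the genome of the 3134 mouse mammary epithelial line, grown without treatment. Brg1 is the catalytic subunit of SWI/SNF complexes, CHD4 that of the NuRD complex and Snf2h that of ISWI complexes, and all 3 move nucleosomes with energy from ATP. Chromatin immunoprecipitation sequencing gave 2 libraries for each remodeler, and each library had its own list of hotspots, the intervals enriched for sequence tags. The lists held 115361 and 260036 hotspots for Brg1, 39797 and 293135 for CHD4, and 32310 and 79969 for Snf2h. They covered 49.7 and 131 Mb for Brg1, 20.9 and 136 Mb for CHD4, and 13.4 and 40.1 Mb for Snf2h. Median widths lay between 366 and 485 bp. The lowest Z score was 2.00 in Brg1 replicate 2 and CHD4 replicate 2 and between 8.50 and 9.49 in the other lists, so the lists differ in threshold as well as in length. The number of tags per library is unknown from these lists. The DNA input libraries were not analysed here. All coordinates are on the mouse mm9 assembly, and annotation at them was not analysed here.

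The first comparison asked how far the 2 libraries of a remodeler marked the same places. For CHD4, 83.4% of the shorter list overlapped the longer one by at least 1 bp, against 11% after random circular shifts along the chromosomes. For Snf2h the share was 58.6% against 2.81%, and for Brg1 it was 49.8% against 9.30%. The 95% Wilson intervals of these shares, which cover counting error only, ran from 83.0% to 83.7%, from 58.1% to 59.2% and from 49.5% to 50.1%. Each share exceeded every shift, with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Merging hotspots that overlapped and keeping the regions with a hotspot from both libraries gave 51805 replicated Brg1 sites, 30521 CHD4 sites and 18232 Snf2h sites. They covered 50.02 Mb, 32.0 Mb and 13.8 Mb. The order of the shares moved with list length: among the 32310 tallest hotspots of every list, the share was 73.2% for Brg1, 66.2% for CHD4 and 44.9% for Snf2h as the mean over both directions. At a common Z score of 9.49 the CHD4 set fell to 18784 sites.

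At the full list lengths, most replicated CHD4 and Snf2h sites overlapped a site of another remodeler. A smaller share of Brg1 sites, the largest set, did so. Of the CHD4 sites, 78.0% overlapped a Brg1 site (95% Wilson interval 77.6% to 78.5%), against 4.09% after shifts. Of the Snf2h sites, 69.3% (68.6% to 69.9%) overlapped a Brg1 site and 69.2% (68.5% to 69.9%) a CHD4 site, against 3.55% and 2.19% after shifts. In the other direction, 46.1% of Brg1 sites overlapped a CHD4 site, 23.8% of Brg1 sites overlapped an Snf2h site, and 40.5% of CHD4 sites overlapped an Snf2h site. Each overlap had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Between single libraries, the share of the shorter list overlapped was 58.4% ± 21.3 for Brg1 with CHD4, 52.2% ± 10.3 for Brg1 with Snf2h and 58.3% ± 10.0 for CHD4 with Snf2h (SD, n = 4 library pairs each). At these list lengths the pairs of remodelers differed by less than the spread between libraries. With every list held to its 32310 tallest hotspots, the shares, averaged over both directions, were 65.7% ± 4.41, 45.3% ± 13.4 and 50.6% ± 12.4. Brg1 with CHD4 then exceeded each of the other pairs by more than either SD, a difference that was not tested. The ranges were 59.7% to 70.0%, 32.1% to 57.2% and 38.3% to 62.0%, so CHD4 with Snf2h reached into that of Brg1 with CHD4. Both low ends were pairs with Snf2h replicate 1, and the Snf2h replicates overlapped each other at only 44.9%. The library pairs reuse the same libraries, so these SDs do not cover independent units. The shares moved with the libraries required. Without Snf2h replicate 1 and replicate 2, the share of Snf2h sites overlapping Brg1 was 41.2% and 46.0% and the share overlapping CHD4 was 33.7% and 44.7%. Without CHD4 replicate 1, the share of CHD4 sites was 16.03% with Brg1 and 5.79% with Snf2h, and 79.4% of Brg1 sites overlapped CHD4. Without Brg1 replicate 1 and replicate 2, the share of Brg1 sites was 11.9% and 23.9% with CHD4 and 6.40% and 11.98% with Snf2h. Without Snf2h replicate 1, 55.8% of Brg1 sites and 78.4% of CHD4 sites overlapped Snf2h. With a site counted from either library, 36.5% of CHD4 sites overlapped Brg1, 15.6% of Brg1 sites overlapped Snf2h and 16.3% of CHD4 sites overlapped Snf2h.

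The series title asks whether remodeling systems overlap, and many regions held replicated sites of all 3. The inputs were not analysed here, and the shifts do not account for background common to the libraries. Overlap of sites therefore does not by itself show that all 3 remodelers bound there. The replicated sites merged into 61081 regions, of which 10081 (16.5%) held Brg1, CHD4 and Snf2h, against a mean of 25.8 and a highest value of 43 over 1000 joint shifts. Shifts limited to 100 kb to 1 Mb gave a mean of 64.8 and a highest value of 139. Another 13043 held Brg1 and CHD4, 2107 held Brg1 and Snf2h, and 2097 held CHD4 and Snf2h. Brg1 alone accounted for 25772 regions, CHD4 alone for 4570 and Snf2h alone for 3411. At 44.7% of the regions there were 2 remodelers or more, against 12.5% without Brg1 replicate 1, 23.2% without Brg1 replicate 2 and 14.9% without CHD4 replicate 1. A second remodeler was present at 49.5% of Brg1 regions, 84.7% of CHD4 regions and 80.7% of Snf2h regions. With the 32310 tallest hotspots of every list these shares were 69.1%, 83.4% and 68.7%. The permutation p for the regions of all 3 was 0.001, the smallest that the shifts can give. The joint shifts moved CHD4 and Snf2h sites separately, so they also removed the overlap of pairs. Of 18232 Snf2h sites, 12631 overlapped Brg1 and 12618 overlapped CHD4, so many had to overlap both. This p therefore lends no support to sharing by all 3 beyond that of the pairs. Regions of all 3 made up 4.55% of all regions without Brg1 replicate 1, 8.42% without Brg1 replicate 2 and 3.98% without CHD4 replicate 1. Without Snf2h replicate 1 their number was 19359, and with the 32310 tallest hotspots of every list it was 6182.

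The smaller classes and the shares depended on requiring both libraries. When 1 library stood for its antibody, all its hotspots counted as sites. Brg1 alone then rose to 224642 regions without Brg1 replicate 1 and 85053 without replicate 2, CHD4 alone to 241840 and 9862 in the same way, and Snf2h alone to 42447 and 14843. Other antibodies' libraries moved these classes too. Brg1 alone was 10328 without CHD4 replicate 1, CHD4 alone was 1399 without Brg1 replicate 1 and 2540 without Snf2h replicate 1, and Snf2h alone was 1536 without Brg1 replicate 1 and 1662 without CHD4 replicate 1. Brg1 with CHD4 was 28308 without CHD4 replicate 1 and 3765 without Snf2h replicate 1. Without Brg1 replicate 1, CHD4 replicate 1 and Snf2h replicate 1 in turn, Brg1 with Snf2h was 3984, 334 and 9042, and CHD4 with Snf2h was 343, 3834 and 4102. A second remodeler was present at 12.5% of Brg1 regions without Brg1 replicate 1, 23.4% without Brg1 replicate 2 and 79.7% without CHD4 replicate 1. Its share of CHD4 regions was 15.4% without CHD4 replicate 1, and its share of Snf2h regions was 43.4% without Snf2h replicate 1 and 51.9% without Snf2h replicate 2.

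**Figure D1:**
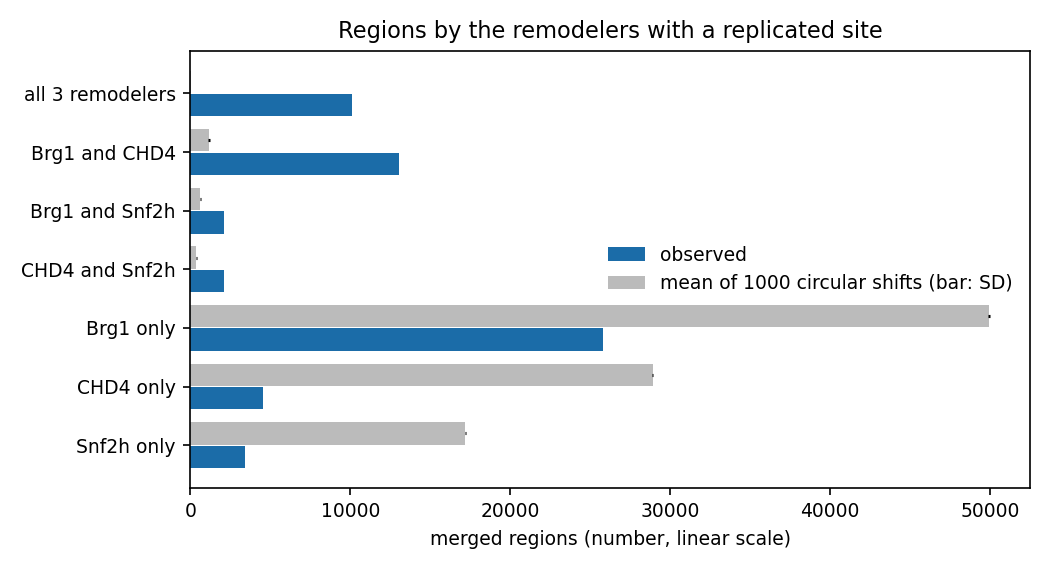
Number of merged regions (horizontal axis, linear) in each class of remodelers (vertical axis), observed in blue and as the mean of 1000 circular shifts in grey, with the SD of the shifts as error bars. Regions of all 3 remodelers numbered 10081 against a shifted mean of 25.8, while each class of 1 remodeler was smaller than its shifted mean. The shifts moved CHD4 and Snf2h sites separately and so also removed the overlap of pairs.

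Snf2h was found with the pair more often than with Brg1 in the absence of CHD4, a comparison chosen after seeing the data. It was present at 43.6% of the 23124 regions holding both Brg1 and CHD4 (95% Wilson interval 43.0% to 44.2%) and at 7.56% of the 27879 Brg1 regions without CHD4 (7.25% to 7.87%). At the 6667 CHD4 regions without Brg1 its share was 31.5%, and it was 19.7% without Brg1 replicate 1, 1.56% without CHD4 replicate 1 and 61.8% without Snf2h replicate 1. The shares at Brg1 regions also moved when a library was left out: they were 83.7% and 32.5% without Snf2h replicate 1, and the second was 1.74% without Brg1 replicate 1, 2.69% without Brg1 replicate 2 and 3.13% without CHD4 replicate 1. The share with CHD4 stayed above the share without it in all 13 alternatives. Regions of all 3 remodelers were also wide, with a median of 1442 bp, against 1130 bp for Brg1 with CHD4, 639 bp for Brg1 alone, 604 bp for CHD4 alone and 528 bp for Snf2h alone. A region spans all sites merged into it, so regions of more remodelers are wider in part by construction. A wider region also has more room for an overlap, and neighbouring regions are not independent, so the intervals cover counting error only. Height was not matched between the compared regions.

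The tallest regions of all 3 remodelers included a pair on chromosome 8, at 20019637 to 20020624 and at 19784321 to 19785311. The first had a maximum tag density of 270 and 142 in the Brg1 libraries, 425 and 280 in the CHD4 libraries, and 564 and 915 in the Snf2h libraries, in the authors' units. It was the tallest hotspot region of both Snf2h lists. The others were on chromosome 2 at 167399647 to 167401004 and on chromosome 11 at 3059416 to 3060243 and at 3064327 to 3066133. The last 2 lie near the tallest region with a replicated Brg1 site alone, chromosome 11 at 3046886 to 3047880, with densities of 152 and 94.3. That region also had a hotspot of 85.2 in CHD4 replicate 2 and of 56.5 in Snf2h replicate 2, so the class names where a replicated site was found and not where other remodelers were absent. Among the tallest regions of CHD4 alone, chromosome 16 at 11143893 to 11144415 had hotspots in the CHD4 lists and no other, at 72.5 and 46.5. The tallest region of Snf2h alone, chromosome 5 at 120972562 to 120973158, reached 72.7 and 150 in the Snf2h libraries and 8.65 in CHD4 replicate 2. At these named regions binding cannot be told apart from background, copy number or mappability, because the inputs were not analysed here. Over whole classes, 33.0% of the regions of Brg1 alone, 17.4% of those of CHD4 alone and 20.8% of those of Snf2h alone had no hotspot in any list of another antibody.

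The next comparison asked whether tall hotspots were shared more often than low ones. They were, in every library. In the lowest decile of maximum tag density, 14.1% of Brg1 replicate 1 hotspots and 18.3% of Brg1 replicate 2 hotspots overlapped a list of another antibody, and in the highest decile 99.3% and 97.7% did. The shares rose from 36.5% to 99.9% in CHD4 replicate 1 and from 17.6% to 96.3% in CHD4 replicate 2. They rose from 17.3% to 99.6% in Snf2h replicate 1 and from 20.2% to 99.7% in Snf2h replicate 2. Height ranked shared above unshared hotspots with a median area under the curve of 0.858 (range 0.683 to 0.926), and the area was on the side of taller shared hotspots in 30 of 30 ordered list pairs, same-antibody pairs included. Tall hotspots are also wide, and with every hotspot set to 500 bp about its midpoint the median was 0.819.

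**Figure D2:**
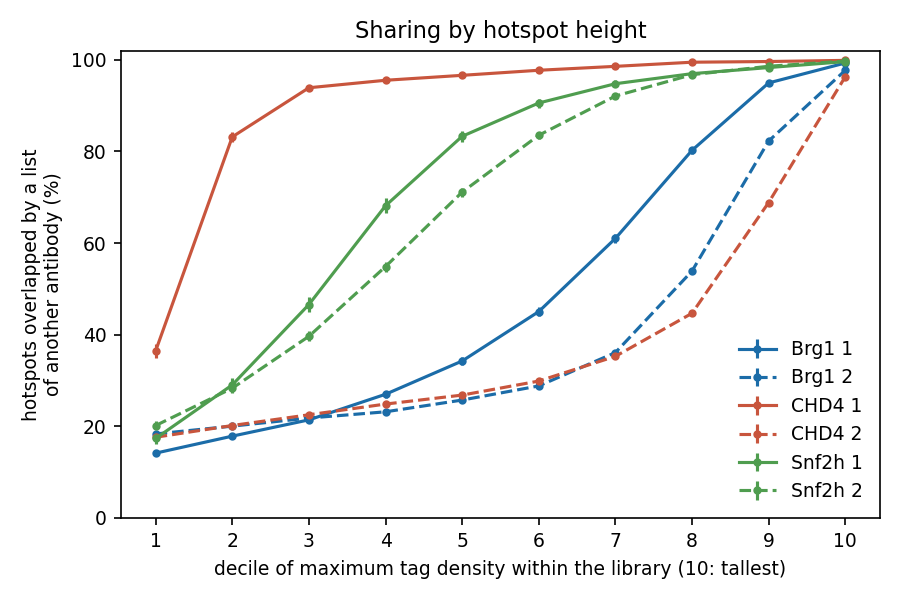
Share of hotspots overlapped by a list of another antibody (vertical axis, percent) in each decile of maximum tag density within a library (horizontal axis, 10 the tallest), with 95% Wilson intervals as bars, solid lines for replicate 1 and dashed lines for replicate 2. All 6 lines end between 96.3% and 99.9%, and CHD4 replicate 1 starts highest, at 36.5%.

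Height differed in order between the remodelers at the places they shared. A hotspot of every list was found in 10442 merged regions, of the 532751 that held a hotspot of any list. Across these regions, which are not independent replicates, maximum tag density ranked alike in libraries of one antibody, with Spearman's rho of 0.768 for Brg1, 0.718 for CHD4 and 0.653 for Snf2h. Between Brg1 and CHD4 libraries rho averaged 0.592 (range 0.567 to 0.626) and between CHD4 and Snf2h libraries 0.389 (0.337 to 0.451). Between Brg1 and Snf2h libraries it averaged 0.108 (-0.0420 to 0.209). Same-antibody pairs exceeded other pairs by 0.350 on average, and this was the highest of the 15 ways to split 6 libraries into 3 pairs (exact permutation p = 0.0667, one-sided). No smaller p is possible with 15 splits, so 0.05 could not be reached.

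Single regions showed these orders. Snf2h stood out on chromosome 1 at 9932222 to 9934912, which ranked at percentiles 73.6 and 85.9 of the common regions in the Snf2h libraries and between 3.54 and 14.5 in the others. CHD4 stood out on chromosome 15 at 72897759 to 72899849, at percentiles 95.1 and 96.8 against 7.94 to 35.6 elsewhere. Brg1 stood out on chromosome 10 at 15807944 to 15808578, at percentiles 66.5 and 83.7 against 0.144 to 9.03. These 3 regions were chosen after their values were seen. Both Snf2h libraries gave the highest 2 of the 6 percentiles at 2260 common regions (21.6%), and both Brg1 libraries did at 1756 (16.8%). Both CHD4 libraries did at 615 (5.89%), below the 6.67% that an even division over the 15 library pairs would give. Some pairs of different antibodies were above the CHD4 pair, such as Brg1 replicate 2 with CHD4 replicate 1 at 730 and with CHD4 replicate 2 at 727.

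**Figure D3:**
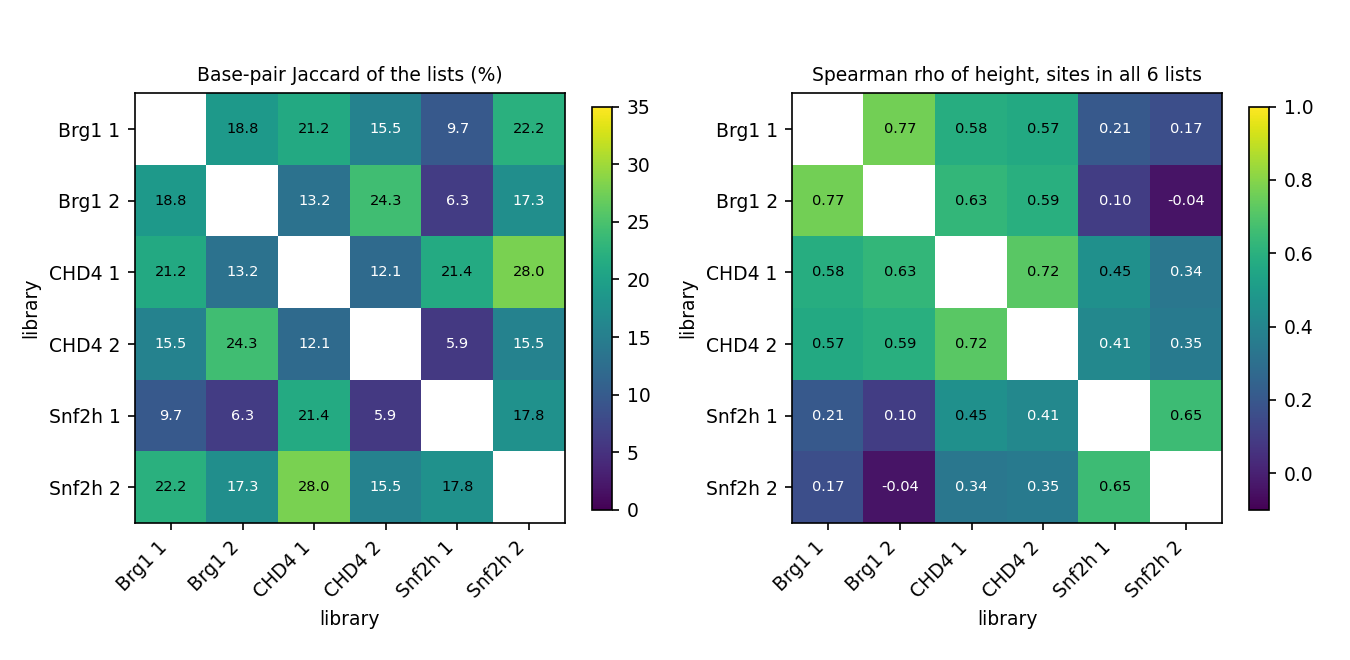
Left, base-pair Jaccard index between each pair of lists (percent), and right, Spearman's rho of maximum tag density over the 10442 regions called in all 6 lists, with libraries on both axes. The highest rho values are the same-antibody pairs, 0.768, 0.718 and 0.653, whereas the highest Jaccard index, 28.0%, joins CHD4 replicate 1 and Snf2h replicate 2.

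By base-pair overlap of the full lists, called positions did not group by antibody as heights did. The base-pair Jaccard index, the length covered by both lists over the length covered by either, averaged 16.2% for same-antibody pairs and 16.7% for other pairs. The difference was -0.487 percentage points, and 8 of the 15 splits gave one as large (exact permutation p = 0.533, one-sided). Brg1 replicate 2 and CHD4 replicate 2, the lists with the lowest Z score threshold, shared 24.3%, more than either shared with its own replicate (18.8% and 12.1%). The index cannot exceed the shorter covered length over the longer one. The 2 CHD4 lists covered 20.9 and 136 Mb, so that pair could not have reached 24.3%. By the share of the shorter list overlapped, the full lists went the other way. That share was 37.3% for Brg1 replicate 2 with CHD4 replicate 2, against 49.8% and 83.4% with their own replicates. Same-antibody pairs were higher by 7.63 points, the highest of the 15 splits (exact permutation p = 0.0667). At a common Z score, 78.4% of CHD4 replicate 2 overlapped Brg1 replicate 2 and 62.3% overlapped its own replicate. Of Brg1 replicate 2, however, 44.0% overlapped CHD4 replicate 2 and 67.8% overlapped its own replicate. The Brg1 and CHD4 lists at this cut still differed in length, from 30396 to 115361 hotspots, so these shares do not rank the pairs. By the Jaccard index of the 32310 tallest hotspots of every list, same-antibody pairs were higher by 3.44 points (exact permutation p = 0.2). With those hotspots set to 500 bp windows they were higher by 4.36 points, the highest of the 15 splits (exact permutation p = 0.0667), so the grouping depended on measure, list length and width.

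The X chromosome carried few sites of any of the 3 remodelers, and chromosome 11 carried many. Replicated sites per Mb on X were 0.338 of the autosomal density for Brg1, 0.388 for CHD4 and 0.421 for Snf2h, the lowest of the 20 chromosomes in all 3 sets. Chromosome 11 was the densest, at 1.52, 1.57 and 1.6 times the genome mean, followed by chromosome 19 at 1.29, 1.31 and 1.32, and chromosome 14 was the lowest autosome at 0.787, 0.773 and 0.705. In the single lists of Brg1 replicate 2 and CHD4 replicate 2, chromosome 11 was at only 1.07 and 1.06, and chromosomes 2 and 3 were densest. It was the densest in the other lists, at 1.24 to 1.47. Regions of CHD4 alone and of Snf2h alone were less depleted on X, at 0.676 and 0.722 of the autosomal density, than regions of all 3 remodelers, at 0.333, or of Brg1 alone, at 0.349, and these differences were not tested. In single lists the X ratio ran from 0.452 in Brg1 replicate 2 to 0.920 in Snf2h replicate 1, where X was the third lowest chromosome. The ratio was therefore higher when 1 library stood for a remodeler: 0.665 without Brg1 replicate 2, 0.585 without CHD4 replicate 2, 0.695 without Snf2h replicate 1 and 0.920 without Snf2h replicate 2.

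**Figure D4:**
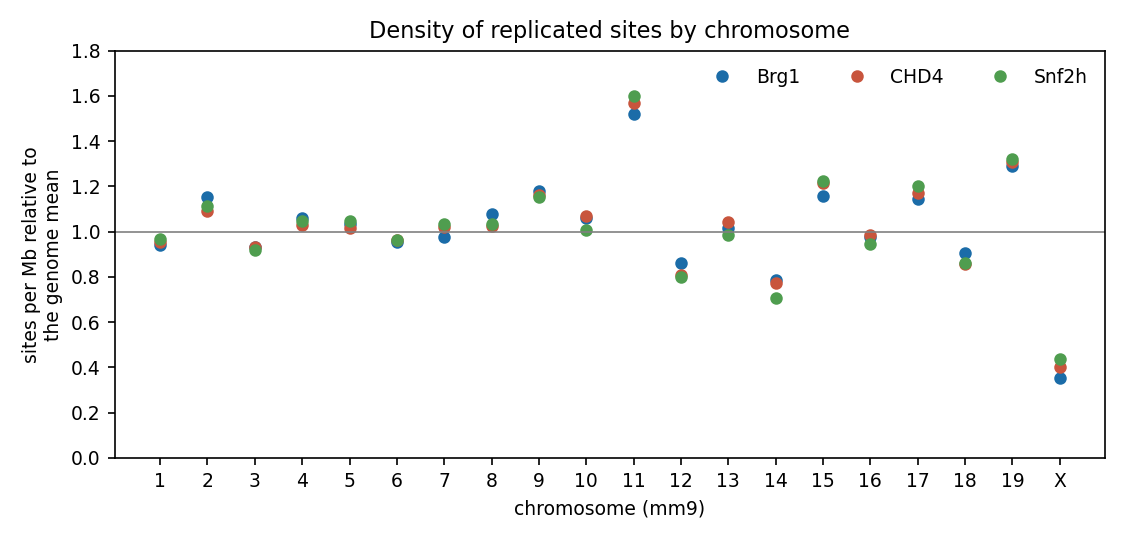
Replicated sites per Mb on each chromosome (horizontal axis, mm9) relative to the genome mean (vertical axis), 1 point per remodeler, with the grey line at the mean. Chromosome 11 lies highest, at 1.52 to 1.6, and X lowest, at 0.352 to 0.437.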

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

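The tests in this part were chosen after the results they bear on had been seen, except that the Jaccard index of lists of equal size and the share of the shorter list in the full lists had been fixed beforehand. At regions common to all 6 lists, the median Z score of X regions relative to autosomal regions was above 1 in both Snf2h libraries (1.11 and 1.09) and below 1 in the Brg1 libraries (0.891 and 0.767) and CHD4 libraries (0.913 and 0.917). The difference between Snf2h and the others was 0.228 on average, and it drew attention because every library of one kind lay on one side. A difference picked in this way must be the highest of the 15 choices of 2 libraries. Its exact permutation p of 0.0667, the smallest possible, was thus fixed by the selection and lends no support.

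The X chromosome had few replicated sites, and at common regions its heights were 0.482 to 0.621 of the autosomal median in the 6 libraries. At a common Z score the X to autosome density ratio of replicated sites was 0.346 for Brg1 and 0.356 for CHD4. These values argue against thresholds that differ between lists as the cause for Brg1 and CHD4. For Snf2h, at 0.409, the cut of 9.49 could hardly change the ratio, because its lists already began at 8.60 and 8.50. The ratios of Brg1, CHD4 and Snf2h were 0.127, 0.149 and 0.224 in lists of equal size. With a site from either library they were 0.548, 0.566 and 0.829. A part played by the height cut or by requiring both libraries is therefore not excluded. Less background DNA from X, through copy number or mappability, stays a candidate explanation: at matched Z score X heights were at most 0.725 of those elsewhere, below every autosome in all 6 libraries, and the inputs that bear on it were not analysed here. Weaker binding on X may add to this for Brg1 and CHD4, whose Z score ratios had upper 95% bootstrap bounds of at most 0.998. How the Z score responds to background DNA is not given in the sources used here, so these ratios cannot separate the explanations. Each bound covers 1 library and not the spread between libraries. For Snf2h, presence and absence of weaker binding cannot be told apart, because the 95% bootstrap interval lay above 1 in replicate 1 (1.03 to 1.17) but not in replicate 2 (0.989 to 1.21), with 241 X regions.

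By the Jaccard index, Brg1 replicate 2 and CHD4 replicate 2 were closer to each other than to their own replicates. By the share of the shorter list they were not in the full lists, at 37.3% against 49.8% and 83.4%. At a common Z score, 78.4% of CHD4 replicate 2 overlapped Brg1 replicate 2 and 62.3% overlapped its own replicate. Of Brg1 replicate 2, however, 44.0% overlapped CHD4 replicate 2 and 67.8% its own replicate, and these lists differed in length. For the Jaccard index, unequal list length alone is argued against, since among the 32310 tallest hotspots of each list their Jaccard index was 49.3%, the highest of the 15 pairs. Hotspot width may account for part: with 500 bp windows in lists of equal size it stood at 32.4%, and the difference from the Brg1 replicate pair was -1.93 points. It still exceeded the CHD4 replicate pair by 5.06 points, which width therefore leaves unexplained. By share of hotspots in lists of equal size, at their own widths, only CHD4 replicate 2 was closer to the other antibody. Of it, 70.8% overlapped Brg1 replicate 2 and 63.1% its own replicate. Of Brg1 replicate 2, 69.2% overlapped CHD4 replicate 2 and 70.1% its own replicate. A shared batch of these libraries is untested, as the labels name none, and so is a real likeness of the bound sites.

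Heights at common regions ranked by antibody, with same-antibody pairs higher by 0.350 in mean rho. On autosomes alone the value was 0.358, but X holds only 241 of the 10442 common regions, so leaving it out could hardly change the value. List length is argued against, since the value was 0.440 at regions of equal-size lists. The real split was 1 of 15 with a value as large, and the highest of the others was 0.228, but 15 splits are too few for a share under 0.05. No test here separates remodeler-specific binding strength from antibody-specific background, and both stay open.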

How the results depend on the processing

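The common Z score, the 500 bp windows, and all alternatives for the X ratio, the height order and the Snf2h share were chosen after seeing the data. Overlap between replicates and between remodelers kept its direction and p under all 6 alternatives for each antibody and all 12 for each pair of remodelers, at 4.83 to 44.1 and 3.20 to 49.8 times the shifts. The excess of Snf2h at Brg1 regions with CHD4, 36.0 points, ranged from 26.4 to 51.2. Height order gave 0.358 to 0.462.

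Same-antibody minus other pairs turned from -0.487 to 3.44 (equal size), 7.63 (share of the shorter list), 4.02 (common Z score) and 4.36 points (500 bp windows of equal-size lists), and the cause was not tested. Regions of all 3 remodelers numbered 6182 with equal size, 6622 with the taller 50%, 39528 with either library, and 10180 to 19359 leaving out a library. Replicated sites fell to 22544 (Brg1) and 20165 (CHD4) with equal size, and CHD4 to 18784 at a common Z score and 18124 with the taller 50%. With 1 library they were 115307 to 259892 for Brg1, 39776 to 292957 for CHD4 and 32303 to 79929 for Snf2h, by construction. Ranking by width gave an area of 0.8004. The X ratio stayed below 1 throughout: for Brg1 0.127 (equal size), 0.548 (either library) and 0.208 (taller 50%); for CHD4 0.149, 0.566, 0.356 (common Z score), 0.109 (taller 50%) and 0.428 (without the tallest 1%); and for Snf2h 0.224, 0.829 and 0.148 (taller 50%). With 1 library it was 0.452 to 0.665, 0.544 to 0.585 and 0.695 to 0.920.

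With the replicate number as a block, pairs of lists with the same number overlapped by 51.7% (Brg1 with CHD4), 52.0% (Brg1 with Snf2h) and 50.9% (CHD4 with Snf2h), and pairs with different numbers by 65.1%, 52.4% and 65.6%, a difference between 2 and 2 pairs that was not tested. As a check of the numbers, mean Jaccard between antibodies went the other way, at 18.2% for the same number and 15.2% for different numbers. In lists of equal size it was 31.1% and 27.9%. The share also moved with list length. Of CHD4 replicate 1 (39797 hotspots), 84.7% overlapped Brg1 replicate 2 (260036), of which 37.3% overlapped CHD4 replicate 2 (293135). The difference in share therefore cannot be read as an effect of the replicate number. The alternatives for promoters, gene lists and motifs were not run. Unknown depth limits any comparison of list lengths.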

Other observations

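Regions of all 3 remodelers were unevenly spread along chromosomes. The median 1-Mb bin held 3, and the fullest held 22, on chromosome 15 from 76000000. Next came chromosome 19 from 5000000 with 21, and chromosome 1 from 92000000 and chromosome 4 from 140000000 with 20 each. Across 2572 bins, which are not independent replicates, the numbers of replicated sites ranked alike, with Spearman's rho of 0.951 for Brg1 and CHD4, 0.900 for Brg1 and Snf2h and 0.914 for CHD4 and Snf2h. These values were computed after seeing the data.

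The tallest hotspot of 3 lists, Brg1 replicate 1 and both CHD4 libraries, fell in the same region, chromosome 17 at 39979738 to 39985836. Its maximum tag density was 647 and 56.0 in the Brg1 libraries, 1160 and 737 in the CHD4 libraries and 130 in Snf2h replicate 2, with no hotspot in Snf2h replicate 1. Chromosome 11 at 108872711 to 108873714 had 383 and 17.1 for Brg1, 366 and 291 for CHD4, 38.5 in Snf2h replicate 2 and no hotspot in Snf2h replicate 1. Whether such heights reflect binding, background, copy number or mappability was not tested, as the inputs were not analysed here.

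Height at matched Z score varied along chromosomes in a pattern common to the libraries. In 5-Mb segments, of which 534 were compared, rho between libraries was 0.882 to 0.978. All 32 segments of X lay below the autosomal median, with a median of 0.550 against 0.969. The lowest autosomal segments were on chromosome 14, from 110000000 at 0.377, from 80000000 at 0.406 and from 90000000 at 0.420. Among whole autosomes, chromosome 14 was lowest in every library, at 0.750 to 0.882, and chromosome 11 highest, at 1.18 to 1.32. Whether this bears on the density of sites on these chromosomes was not tested.

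In the lowest decile of height, hotspots were denser on X than on autosomes in 4 lists, by 2.75 times in Brg1 replicate 1, 3.25 in CHD4 replicate 1, 5.99 in Snf2h replicate 1 and 2.83 in Snf2h replicate 2. In Brg1 replicate 2 and CHD4 replicate 2, whose lists reach a lower Z score, the ratios were 0.676 and 0.663. Hotspots of equal height were put in deciles in chromosome order with X last, so ties can lower the X ratio of the lowest decile. In the next decile the ratios of these lists were 0.604 and 1.08. How far ties account for the contrast with the other lists was not tested. In the highest decile the ratio was between 0.0260 and 0.160 in all 6.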
